A study of Homo sapiens with 2 samples.

How the data were processed

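Gene expression was measured on 2 Affymetrix whole-transcript arrays, 1 of untreated HT-29M6 cells and 1 of HT-29M6 cells treated with prostaglandin E2 (PGE2) for 16 hours. Per the labels' protocols, 100 ng of total RNA from each sample was labelled with biotin by a whole-transcript reagent kit. The group of each array was taken from its source name, which the description and the stated design of the series repeat. The title of the treated array instead names TGF and 2 hours, and the labels do not resolve this conflict. No label says that either group held more than 1 culture, so no test between conditions could be made and no p-value for a gene is given.

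The authors deposited 1 table of 53617 rows with 1 log2 value per row and array, made with RMA in R 3.1.1 per the submitters' processing notes. RMA corrects the background, equalises the distribution of probe signals between arrays and summarises the probes of a row on the log2 scale. The log2 scale was taken from the values, which ran from 0.833 to 13.9. The sorted values of the 2 columns differed by at most 0.0987, so a shift common to all genes would not be visible after this step. Which arrays were normalised together, and the genome build, are not given in the sources used here. Scanner files were not used here, so background flags and probe numbers per row are unknown, and low values may be at the background. The number of arrays limits the precision of every value.

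Rows were named through a table pairing 16098 rows with 1 gene symbol each. No row had several symbols, and 37519 rows were not listed and stay unnamed here. All 16098 Entrez identifiers matched the RefSeq gene table of assembly GRCh38.p14, and 0 symbols needed updating. The named rows gave 14884 genes, of which 11916 are protein-coding. For the 779 genes with several rows, the row with the higher mean of both arrays stood for the gene; rows of 335 genes differed in sign. The pairing of rows with names was taken as given, and levels of different rows are not compared.

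All rules were written before the data were examined, except where stated. The difference was the PGE2 value minus the control value. The size rule counted a gene when this difference was at least 1 on the log2 scale, a 2-fold difference, and its higher value reached a floor of 5.93, the median of the higher values over named rows. The text names the 12 genes with the largest positive and the 12 with the largest negative difference above the floor, leaving out small RNAs, provisional names, Y-linked genes and XIST. It also draws on the up to 4 members of each gene list with the largest difference, and on 13 genes fixed by name, of which 7 were listed. The others, among them PTGER1, PTGER2, CDH1 and AREG, were not analysed here.

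A total of 21 gene lists was fixed in advance, and 277 of their 431 distinct symbols were listed. The median difference of a list was placed among 10000 random lists of the same size, drawn from the same 20 bins of mean level. A list was said to stand apart below percentile 2.5 or above percentile 97.5, as a description of these 2 arrays and not as a test of conditions. With 21 independent lists, 1.05 would stand apart by chance. The procedure was tested on simulated data made from the levels and spreads of this comparison. Of 200 simulated lists of 13 unchanged genes, 6% stood apart; of 200 lists shifted by 0.2, 98.5% did. Over the 7578 genes at or above the floor, the size rule counted 100% of simulated changes of 1.5, 3% of changes of 0.7 and 0 unchanged genes. The simulated differences were normal and independent between genes. Genes that vary together and outlying single rows were not represented, so unaffected lists or genes may be called more often in the real arrays.

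The alternatives were 1.5-fold and 3-fold size thresholds, no floor or a floor at percentile 75, the mean of a gene's rows, loess centring with a span of 0.3, median centring, an offset of 16 on the linear scale, list members above the floor, and random lists not matched on level. Matching random lists also on the genomic span of genes, in 10 level bins and 5 span bins, was added after seeing the data. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.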

Results

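The data comprised whole-transcript expression profiles of HT-29M6 cells, a mucus-forming subline of the HT-29 colorectal adenocarcinoma line that resists 1 µM methotrexate. One array held untreated cells and 1 held cells exposed to PGE2 for 16 hours. PGE2 is a lipid mediator that acts on cells through the EP receptors, encoded by the PTGER genes. The series belongs to a study of how fibroblasts expressing the transcription factor SNAI1 act on tumour cell invasion, and the comparison asks which transcripts of the tumour cells differ after PGE2. There were no replicates, so each value below is a single array value on the log2 scale, and each difference is PGE2 minus control. The treated array's title names TGF and 2 hours in place of PGE2 and 16 hours, so directions below are those of the array labelled PGE2 in its source name.

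Few named genes differed by much between the arrays. The median signal was 4.85 in each, as the authors' normalisation sets it. Among the 7578 named genes at or above the floor of 5.93, 88.9% differed by at most 0.2, and the standard deviation of the differences across genes was 0.13. This spread narrowed with signal level, from 0.28 in the lowest 10% of genes to 0.09 in the highest 10%. Different rows of the same gene disagreed by a median of 0.14, highest less lowest, over the 779 genes with several rows. That median covers genes at any level and includes identical rows. Across 137 genes with a pair of non-identical rows above the floor, the differences of the rows correlated weakly (Pearson r = 0.27, two-sided permutation p = 0.0015; Spearman rho = 0.20, two-sided permutation p = 0.019), with genes not being independent replicates. These spreads describe the arrays, not the variation between cultures, and the correlation was not among the rules written beforehand.

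One gene, MKRN1, met the size rule of a 2-fold difference, and it was higher in the PGE2 array. MKRN1, a RING-type ubiquitin ligase, had a signal of 5.31 in the control and 6.39 with PGE2, a 2.11-fold difference. Its control value lay below the floor, and with an offset of 16 on the linear scale its difference was 0.84, under the rule. MKRN1 has processed copies elsewhere in the genome, and which copies its row reads is not known here. No gene met the rule in the lower direction. No p-value can be attached to either count.

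The next genes on the higher side differed by less than 2-fold. The pseudogenes CES1P2 and TTC3P1 were 0.77 and 0.74 higher, and both resemble a parent gene closely enough that their rows are uncertain. NKAP, a regulator of transcription and splicing, was 0.66 higher. PRM2, which encodes a sperm protamine, was 0.57 higher, and the zinc finger gene ZBTB47 was 0.53 higher. The pseudogene ESPNP was 0.51 higher, and SPRR2A, a component of the cornified envelope of squamous epithelia, was 0.50 higher. POLK, the translesion DNA polymerase kappa, was 0.48 higher, with its other row at 0.45. CSH2, ADAM11 and ZNF268 completed the 12 with differences of 0.46, 0.46 and 0.45. Of these 12 genes, only TTC3P1 had a control signal above the floor.

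On the lower side, YPEL3, a p53-regulated growth suppressor, went from 7.69 to 7.11, a difference of -0.58 where genes of its level had a standard deviation of 0.12. TRAIP, a ubiquitin ligase acting at replication forks, differed by -0.55, and VWA5B2 by -0.54. The mast cell tryptase genes TPSB2 and TPSAB1, near-identical copies whose rows are therefore uncertain, differed by -0.49 and -0.42. GON7, a subunit of the tRNA-modifying KEOPS complex, differed by -0.49. B9D2, a protein of the ciliary transition zone, differed by -0.47, CABP7 by -0.47 and FERMT3, which encodes kindlin-3, by -0.46. MFF, a mitochondrial fission factor, differed by -0.44, FOXRED1, a complex I assembly factor, by -0.44, and the homeobox gene ALX4 by -0.42. Among the 12 lower genes, only YPEL3, TPSAB1, B9D2 and MFF had a signal above the floor in the PGE2 array.

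**Figure D1:**
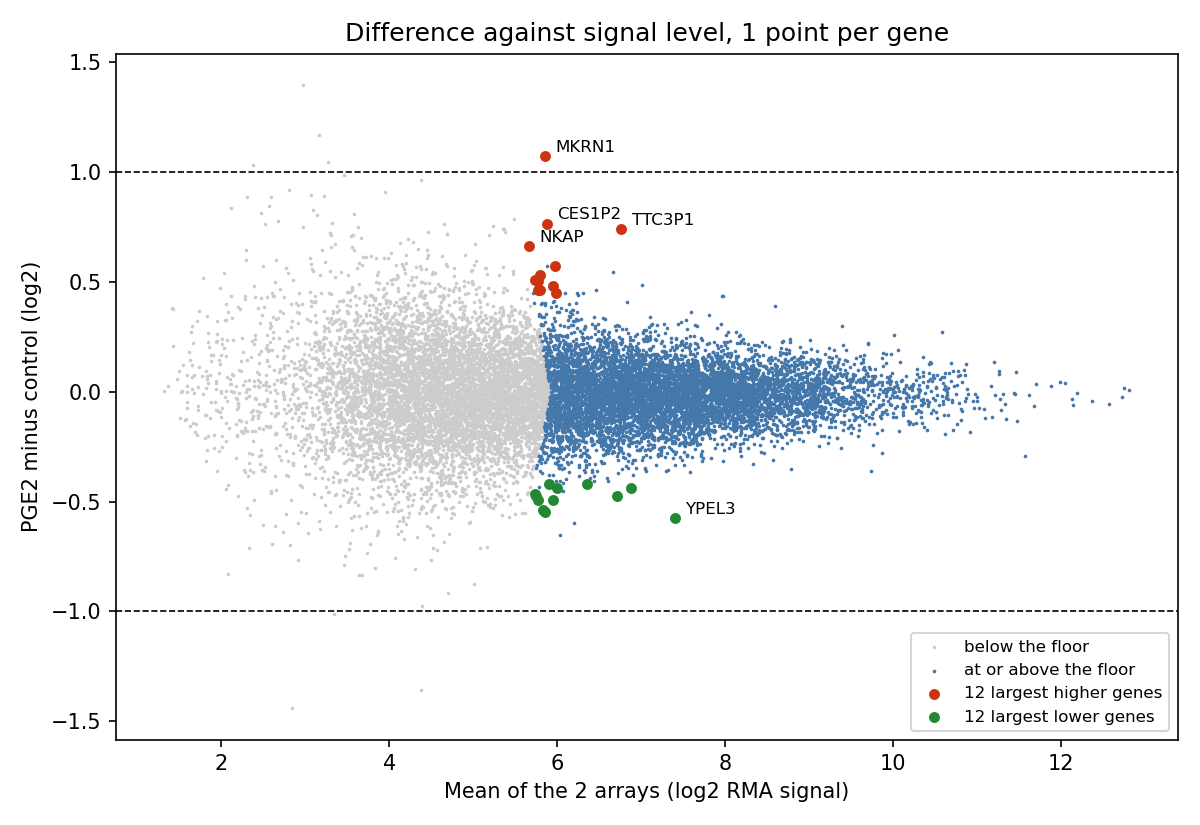
Each point is 1 of 14884 named genes, with the mean log2 RMA signal of both arrays on the x axis and the log2 difference, PGE2 minus control, on the y axis; dashed lines mark differences of 1 and -1, and colours mark genes below the floor, at or above it, and the 12 largest in each direction. The spread narrows to the right, and MKRN1 is the only gene at or above the floor beyond a dashed line.

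Transcripts of the PGE2 pathway itself differed little. Of the 13 listed genes of prostaglandin reception and metabolism, 5 were higher and 8 lower, none by 1 or more, with a median of -0.07 (interquartile range -0.10 to 0.02) at percentile 12.6 of random lists. The receptor gene PTGER4 had a signal of 4.45 in both arrays, and PTGER3 went from 3.83 to 3.97, all below the floor. PTGS2, the inducible cyclooxygenase, went from 7.93 to 7.83, and HPGD, which inactivates prostaglandins, from 6.82 to 6.72. The largest differences in the list were those of PTGFR, 0.35, and PTGDR, -0.27, both below the floor.

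The listed targets of the pathways downstream of EP receptors also stayed within the range of random lists. Of the 21 cAMP and CREB targets, 9 were not analysed here, among them NR4A1, NR4A2, NR4A3 and PDE4D. Of the 20 NF-kappaB targets and chemokines, 8 were not analysed here, among them NFKBIA and TNFAIP3. The 12 listed cAMP and CREB targets had a median of -0.06 (interquartile range -0.10 to 0.04; percentile 16.4), with 4 higher and 8 lower. CREM, a cAMP-responsive transcription factor, was 0.23 higher, while the immediate early genes JUNB and EGR1 differed by -0.17 and -0.10. The 10 members at or above the floor had a median of -0.02 (percentile 42.3). Among 14 EGFR ligand and ERK feedback genes the median was -0.01 (interquartile range -0.15 to 0.04; percentile 50.7), and the ligand genes EREG and BTC differed by -0.19 each. The 16 Wnt and beta-catenin targets had 8 members higher and 8 lower, at percentile 61.1. Their stem cell genes went both ways, ASCL2 by 0.18 and LGR5 by -0.15. The 12 NF-kappaB targets and chemokines lay at percentile 44.3, with CCL20 at 0.39 and CXCL8 at 0.35, both from control signals of 3.93 and 4.11, below the floor.

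The TGF-beta and SMAD targets, which bear on the title of the treated array, lay at percentile 83.2. Their 8 listed members of 20 had a median of 0.03 (interquartile range -0.01 to 0.07), and the largest difference was 0.10, of SKI. The early targets SMAD7 and SKIL were at 5.92 and 8.91 in the control, and they differed by 0.02 and 0.09. KLF10 differed by -0.09.

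Genes of epithelial identity and invasion showed no member past the size rule. SNAI1 went from 6.04 to 5.91, a difference of -0.13, and the intermediate filament gene VIM differed by -0.16 from a control signal of 6.16, with its 3 rows running from -0.16 to 0.0045. The 13 mesenchymal and EMT genes had 10 members lower and 3 higher, with a median of -0.08 (interquartile range -0.16 to 0.00) at percentile 15.6. Only 3 of the 13 reached the floor, with a median of -0.16 (percentile 9.09). The 20 epithelial junction and keratin genes all reached the floor and had a median of -0.02 (interquartile range -0.10 to 0.03; percentile 40.3). Within them KRT8 differed by -0.28, CLDN4 by -0.19 and CLDN7 by -0.18, while TJP1, encoding ZO-1, was 0.13 higher. The 13 invasion proteases and inhibitors lay at percentile 74.4. Their largest differences, MMP13 at 0.41, MMP10 at 0.33 and MMP1 at 0.24, were at signals below the floor.

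Of the lineage lists, that of goblet cell and mucin genes was the 1 of all 21 lists to stand apart. Its 11 listed members had a median of -0.10 (interquartile range -0.12 to -0.06), at percentile 1.33, with 9 lower and 2 higher and no member past the size rule. The other 10 of its 21 members, the MUC mucin genes of the list among them, were not analysed here. FCGBP, a mucus-associated protein, differed by -0.21, the trefoil factor gene TFF3 by -0.14, and GALNT12, which starts mucin-type O-glycosylation, by -0.11. CLCA1 differed by -0.14, below the floor. The list no longer stood apart when random lists were not matched on level (percentile 4.92) or were matched on level and genomic span (percentile 4.405). Among 21 independent lists, 1.05 would stand apart by chance.

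The 17 absorptive colonocyte genes lay at percentile 85.6 and went both ways. GUCA2A, encoding guanylin, went from 9.92 to 9.56, a difference of -0.36 at a level where the standard deviation across genes was 0.09. CEACAM5 and CEACAM6 were 0.31 and 0.23 higher, from 7.80 and 7.61, while CEACAM7 differed by -0.35 below the floor; CEACAM6 was added after its values were seen. The 14 enteroendocrine genes, of which 1 reached the floor, lay at percentile 88.6, with CHGA at 0.19 and CHGB at 0.21.

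The 26 cell cycle genes had 17 members higher, a median of 0.03 (interquartile range -0.01 to 0.08) and percentile 93.6. The proliferation marker MKI67 and TOP2A were each 0.17 higher, PCNA was 0.16 higher, and CCNE2 differed by -0.24. With only the 25 members at or above the floor the list reached percentile 98.3, past the upper limit. Matching on level and span, added after seeing the data, gave 98.9. It stayed inside the limits at 84.65 with random lists not matched on level and at 92.51 with the mean of a gene's rows. The 13 unfolded protein and amino acid stress genes had a median of -0.06 (interquartile range -0.15 to -0.03; percentile 7.35), with 10 lower. DDIT3 went from 4.93 to 4.21, below the floor in both arrays, while TRIB3 and ATF4 differed by -0.17 and -0.15.

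The remaining metabolic lists stayed near their random ranges. The 10 hypoxia and glycolysis genes lay at percentile 79.1, where PGK1 was 0.44 higher, from 7.76 to 8.20, and VEGFA differed by -0.19. The 13 cholesterol synthesis genes lay at percentile 71.7, with HMGCS1 0.15 higher and PMVK at -0.19. The 7 listed folate genes lay at percentile 60.3, and their largest difference was 0.14, of FPGS. The 13 interferon response genes lay at percentile 90.3, with a median of 0.07 and IFIT1 going from 3.38 to 3.96, below the floor. The 4 members at or above the floor had a median of the opposite sign, -0.08, at percentile 21.2.

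Markers of other cell types gave no list that stood apart. The 7 listed fibroblast markers had a median of -0.02 (percentile 45.3), and the collagen genes of that list were not analysed here. MFAP5 differed by -0.41 and TAGLN by 0.18, both below the floor. The 10 leukocyte and endothelial markers lay at percentile 22.2, with PECAM1 going from 4.88 to 4.12 below the floor. The 16 cytosolic ribosomal protein genes, a check of scaling, had a median of -0.04 (percentile 16.4), with RPL6 at 0.29 and RPS6 at -0.17.

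**Figure D2:**
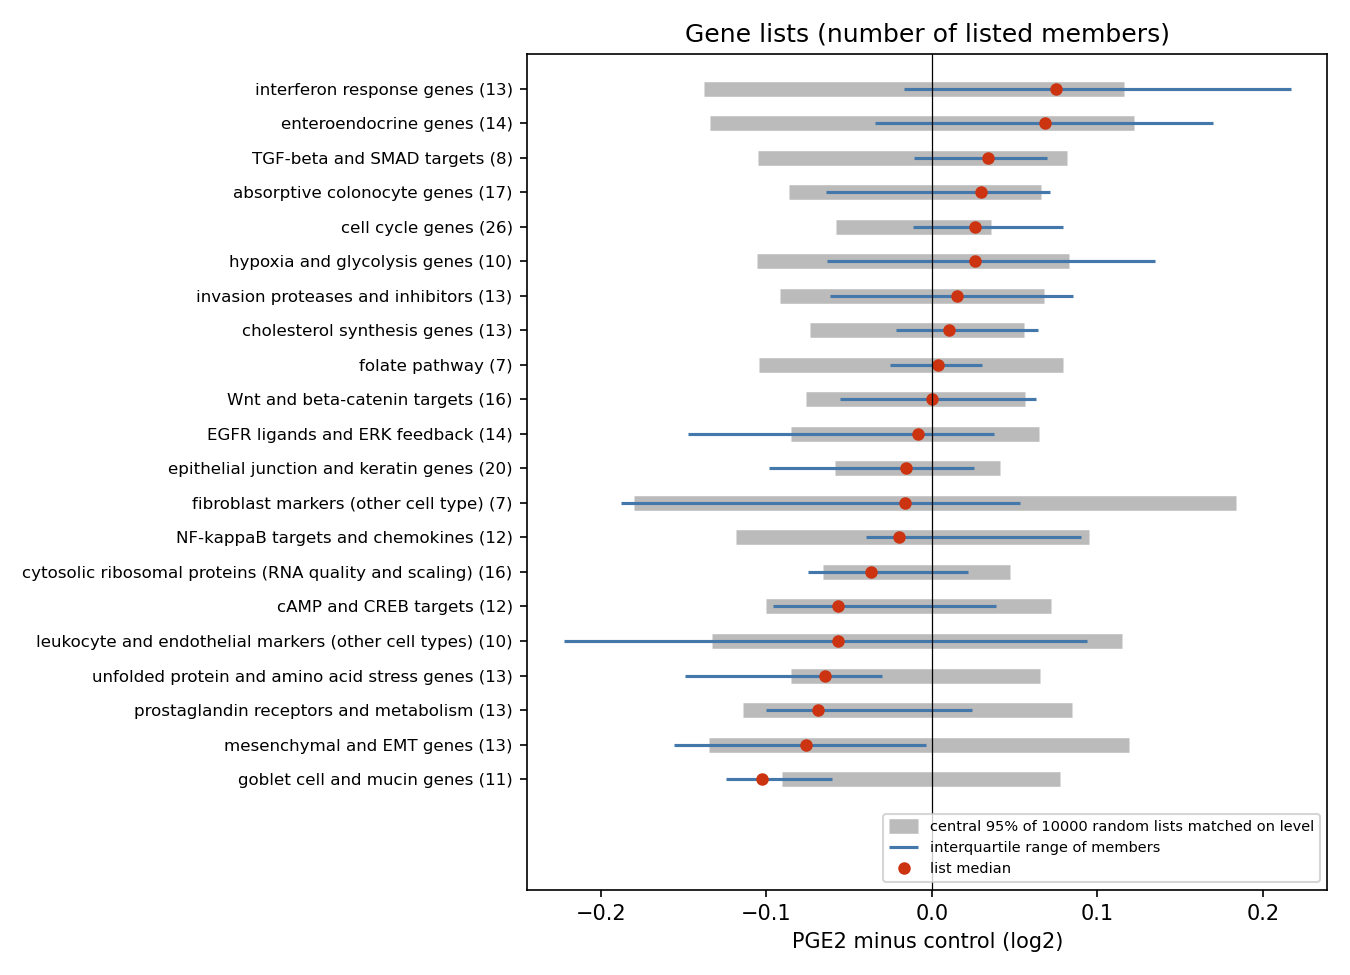
Median log2 difference, PGE2 minus control, of each of the 21 gene lists (points), with the interquartile range of the members (thin lines) and the central 95% of 10000 random lists matched on signal level (grey bars); the number of listed members is in parentheses. Medians run from -0.10 to 0.07, and that of the goblet cell and mucin genes lies outside its grey bar.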

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

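Rows without a gene name enter no gene comparison above, and some of them differed between the arrays in both directions. Of the 8507 such rows at or above the floor, 20 were at least 1 log2 unit higher in the PGE2 array and 13 at least 1 lower, against 1 and 0 of the 7578 named genes. At any level, 524 of the 37519 unnamed rows differed by at least 1, against 5 higher and 3 lower of 14884 named genes. Among the unnamed rows at or above the floor, the extreme ones on the higher side were 16993425, from 4.29 to 6.02, and 16653359, from 4.75 to 6.39. On the lower side they were 16654203, from 6.09 to 4.30, and 16655337, from 7.02 to 5.31. Without gene names and probe numbers these values have no further reading here.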

How the results depend on the processing

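The count of 1 higher and 0 lower genes was the same with the mean of a gene's rows, loess centring and median centring. A 1.5-fold threshold gave 4 higher (MKRN1, CES1P2, TTC3P1 and NKAP) and 2 lower (SCARNA11 and MIR1299, named after their values were seen). With a 3-fold threshold, a floor at percentile 75 or an offset of 16, 0 genes were higher, since MKRN1 then fell short by construction. Without a floor, 5 were higher (MKRN1 and the microRNA genes MIR4503, MIR520D, MIR3649 and MIR3914-1) and 3 lower (GOLGA6L4, MIR200C and LINC02297), all named after their values were seen; the cause was not tested. The goblet cell list moved from percentile 1.33 to 4.92 without matching on level and to 4.405 with matching on level and span, the latter chosen after seeing the data. The cell cycle list moved from 93.6 to 98.3 with members above the floor and to 98.9 with matching on level and span. The other 99 of 103 list results stayed on their side of the limits, though with members above the floor the interferon list median turned from 0.07 to -0.08 (4 genes) and the Wnt median from 0.00034 to -0.0075. The enteroendocrine and fibroblast lists had 1 member each above the floor, and this alternative was not run for them. Of 342 repeated differences of 114 named genes, 338 moved by less than the standard deviation at their level and the 1 called difference, of MKRN1, kept its sign; PTGER4 changed from 0.0010 to -0.0022 with loess centring. The other 4 shrank under the offset of 16, MKRN1 to 0.84, DDIT3 to -0.43, IFIT1 to 0.26 and PECAM1 to -0.45. Loess centring moved no gene by more than 0.0163, so list medians nearer 0 than this have no direction. Medians farther from 0 but inside the range of their random lists have no settled direction either. No paired analysis was possible because each group has 1 array, and for the same reason no replicate could be left out. Signal over background is unknown here, and differences below the floor are the least reliable.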

Other observations

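The families and the tests of the treated array's identity in this part were chosen after seeing the data. The tests on genomic span and on MIR200C were set after the patterns were seen but before their outcomes were. The comparisons of chromosomes and of MKRN1 with genes and rows of its level were not among the rules written beforehand. Of 28 gene families defined by name and holding at least 8 coding genes, 8 stood apart from random lists matched on level. For independent families chosen beforehand, 1.4 would stand apart by chance. These families were chosen after seeing the data, so their count cannot be read as an excess over that rate. Mitochondrial ribosomal proteins had 47 of 73 members lower (median -0.06, percentile 0.04), led by MRPL4 at -0.33 and MRPL11 at -0.29. The TMEM genes had 131 of 211 lower (median -0.05, percentile 0.05), and the genes named EIF had 17 of 24 lower (median -0.07, percentile 1.01). The largest difference among the genes named EIF went the other way, EIF5B at 0.30. On the higher side, 24 of 31 DEAD-box helicases were higher (median 0.07, percentile 99.8), with DDX59 at 0.28, below the floor, and DDX23 at 0.24, while DDX51 was at -0.25. Kinesins had 23 of 39 higher (median 0.05, percentile 99.4). KIF14, a mitotic kinesin, was 0.18 higher, while KIF6, below the floor, was at -0.19. Genes named CENP, genes named HSP and protocadherins lay at percentiles 98.2, 98.9 and 98.7. Of these, 11 of 16, 14 of 18 and 16 of 29 were higher, so 13 protocadherins were lower. The largest protocadherin difference, PCDHB4 at 0.67, was below the floor. None of these families had a member past the size rule. With matching on level and span, 9 families stood apart, the mitochondrial ribosomal proteins moved to percentile 4.18 and the DEAD-box helicases stayed at 99.9.

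Among 7016 coding genes at or above the floor, genes of longer genomic span had higher differences (Spearman rho = 0.22 across genes, which are not independent replicates). The median difference was -0.05 in the shortest 20% (median span 4.86 kb) and 0.03 in the longest 20% (median span 142 kb). Uneven normalisation along signal level is argued against, because the relation was present at a fixed level, with a median rho within 10 bins of signal level of 0.28, though rho was only 0.069, 0.0042 and 0.083 in the 3 lowest bins. A background effect that needs no transcript is also argued against: the slope per doubling of span was -0.00084 in the lowest 25% of coding genes by signal (upper 95% limit 0.0026) against 0.013 at or above the floor, and rho reached 0.39 in the highest of the 10 bins, a value added afterwards. Other array effects, among them any that grow with signal, were not tested. Also open and untested are a difference in RNA integrity or labelling between the samples, a difference between the cultures, and the PGE2 treatment itself. They stay open since each group has 1 array.

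Median differences of 23 chromosomes, over the same genes, fell with the density of coding genes (Pearson r = -0.66, two-sided permutation p = 3e-05; Spearman rho = -0.79, two-sided permutation p = 4e-05). The medians ran from -0.03 on chromosome 19 to 0.02 on chromosome 13. Without chromosomes 17 and 19, the farthest in density, r was -0.85 (p = 1e-05, the smallest that 100000 permutations give). Chromosomes are not independent samples, and this relation and that with span were not separated. The comparison was not planned beforehand, so its p-values are descriptive only.

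The lists that match the treated array's source name and its title both stayed within the range of random lists. The TGF-beta and SMAD list lay at percentile 83.15 and the cAMP and CREB list at percentile 16.36, so neither a 2-hour TGF treatment nor a PGE2 response at 16 hours can be told apart from the other or from no response. What keeps this open is that 8 of 20 and 12 of 21 members were listed, that HT-29 cells are known for a defective SMAD4 gene, and that many cAMP targets are transient.

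Among 1126 small RNA genes, which the naming rule left out, none of the 194 at or above the floor met the size rule. Below it, MIR200C, a microRNA of epithelial cells, went from 5.06 to 3.70. A lower shared primary transcript would lower MIR141 too. The rule set beforehand counted a MIR141 row not lower by more than 1 standard deviation of small RNA rows (0.28) against this. The MIR141 row differed by 0.0908, so by that rule the explanation failed. However, this row is also below the floor, which the rule did not take into account, and it excludes nothing. Row noise was tested on the 728 other small RNA rows down to 1 log2 unit below its level, with no upper limit. Of these, 0 differed by as much and 10 by at least 50% as much (MIR568 by -0.88). The 4 small RNA genes at least 1 higher in the PGE2 array lay under that cutoff, and spread narrows with level. These counts may therefore understate row noise at the level of MIR200C. They leave open both a change of MIR200C and noise of its own row. MIR200A, MIR200B and MIR429 differed by -0.21, 0.23 and -0.25.

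MKRN1 was the 1 of 2905 named genes within 0.5 of its level to differ by as much, while 18 of 4825 unnamed rows in that band (0.37%) did. MKRN1 was also the only named gene to meet the size rule. Its standing alone in this band follows almost wholly from that and adds no support.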
